A study of Capsella rubella and Arabidopsis thaliana with 32 samples.

How the data were processed

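The series held 32 samples of Arabidopsis thaliana (accession Col-0) and Capsella rubella (line Cr1GR1). The mutant was nrpd1a (allele nrpd1a-3 in Arabidopsis per the labels), which lacks the largest subunit of RNA polymerase IV (Pol IV), the plant polymerase that starts the making of 24-nt small interfering RNAs (siRNAs). In Capsella the labels call it pol4. Small RNA was sequenced from Arabidopsis microspores, Capsella microspores and 1-month Capsella leaves, polyadenylated RNA from microspores of each species, and bisulfite-treated DNA from 1-month Capsella leaves, each with 2 nrpd1a and 2 wild-type (WT) libraries. Microspores, the young male spores that divide to become pollen, were enriched on Percoll gradients per the labels, and each bisulfite library pooled leaves of several plants. Leaf genomes of 1 WT plant and 5 nrpd1a plants, aged 2 months, were also sequenced. Arabidopsis pollen of rdr2 and rdr6, mutants of RNA-dependent RNA polymerases, gave 1 small RNA library each and had no WT library; their labels give Col-0 as genotype, and the mutants named in title and source were used. Groups and replicate numbers were taken from the labels.

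The deposited small RNA files listed each distinct read sequence with its raw read count and its length, with no genome position. The deposited microspore RNA tables gave RPKM, reads per kilobase of feature and 1000000 reads, for genes and for annotated transposable elements, by the authors. The denominator of the RPKM was not stated. In both tables the element values summed to more than the gene values, so changes of elements were also computed after bringing them to the denominator of the genes; that denominator was estimated from the most frequent ratio of the smallest values between libraries. The deposited bisulfite files listed methylated and unmethylated read counts per cytosine in the CG, CHG and CHH contexts (H is A, C or T). The deposited insertion table gave, for each position and plant, the identifier of the element called as inserted there, with no read support. Per the submitters' processing notes, TopHat2 2.1.0 and Bismark (version not given) were used, and TAIR10 was the only genome build named. The Capsella build is not given in the sources used here. Bisulfite conversion rates, adapter trimming and the insertion caller were not given either. The units were checked against the values of the files, and no per-sample column was left unused (0 columns).

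Choices in this paragraph and the next were made before the data were examined, unless a sentence says otherwise. Shares of small RNA reads by length were taken over all reads of a library and compared with a two-sided exact permutation test, which cannot give a p under 0.333 for 2 against 2 libraries. Shares of single pollen libraries carry 95% Clopper-Pearson intervals. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. Read counts per sequence, for 21 and 22 nt together and for 24 nt, were tested with edgeR 4.0.16 (quasi-likelihood F test) on sequences with at least 10 reads in at least 2 libraries. A sequence could pass this filter through the WT libraries alone, which favours falls in advance. Library size was the total of all reads, without TMM. A difference of the genotype effect between Capsella microspores and leaves was tested as an interaction term. Fold changes against libraries with 0 reads are lower bounds, taken at 3 reads over the group. Mature sequences of 37 conserved microRNAs and 2 TAS3 siRNAs, written from textbook knowledge after the small RNA files were seen to hold sequences alone, were looked up by exact match.

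RNA-seq was tested with limma 3.58.1 (moderated test with a mean-variance trend) on log2(RPKM + 1) for genes, and separately for elements, with at least 1 RPKM in at least 2 libraries. The 10 gene lists were tested with camera at a preset correlation of 0.01 and also counted with p-values adjusted over the list alone. Lists could be tested in Arabidopsis only, because none of the Capsella gene identifiers (0 matched) occurred in the annotation at hand and the files do not pair them with names. For the same reason the correlation between the species over orthologs, the lists by product name and the overlap of gene and siRNA changes could not be computed. Methylation levels are methylated reads over all reads at cytosines covered at least 4 times. Levels by trinucleotide, by scaffold and by CHG level of windows were taken over all reads at any coverage, a choice made after the coverage was seen, the last in windows of at least 5 listed cytosines and 10 reads per context in each library. Windows were grouped by the CHG level of 1 WT library, chosen after seeing the data, so that no compared library set the grouping. Such a grouping picks windows methylated in WT, which favours losses in nrpd1a. A grouping by the mean CHG level of all libraries is therefore given beside it. Windows of 300 bp with at least 5 such cytosines in each library were tested with edgeR on methylated and unmethylated counts. Those without a methylated or without an unmethylated read over all libraries were left out, a step not fixed beforehand. A window was called at an adjusted p under 0.05 and a minimum difference of group means. This minimum was 35 percentage points for CG, 20 for CHG and 10 for CHH. Insertions per plant were compared with a two-sided exact permutation test, which cannot go below 0.167 for 5 plants against 1. All adjusted p-values are Benjamini-Hochberg values and were called at 0.05. Computations used R 4.3.3, DESeq2 1.42.0, the data.table package (1.17.8), Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and Matplotlib 3.10.9.

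Named genes followed a fixed rule. NRPD1 came first, then the 15 largest rises and the 15 largest falls per species among genes past the threshold whose libraries did not overlap, then list members past the threshold and up to 4 members with the smallest p per list. For sequences the rule took the 5 largest falls and rises per tissue and size class, for windows the 3 largest losses and gains per context, and for elements all with at least 3 positions. Only the first 2 identifiers per direction are printed for genes outside the lists. Sequences that rose are given as counts.

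Alternatives tried were other denominators, scalings, filters, pseudocounts, tools, coverage minimums, window sizes, set tests and tests, a fit with replicate numbers as pairs, and leaving out each library or plant in turn. Added after seeing the data were scaling to the known microRNA sequences, drawing every library down to the smallest, differences of shares and levels within replicate numbers, requiring at least 20 WT reads in each tissue, setting the medians of all genes equal, the gene denominator for elements, methylation over all reads or over cytosines covered in every library, and merging insertion positions within 100 bp. The fits of genes, elements, sequences and windows and the interaction were tested on simulated data with known changes. With 100 changed members each unless stated, a log2 change of 5 was recovered for 88% to 100% of small RNA sequences and for 100% of genes, and a log2 change of 2 for 7% to 68% of sequences and 65% to 76% of genes. In the interaction a log2 change of 5 in microspores alone was recovered for 24% of sequences of 21 and 22 nt and 14% of 24 nt, and one of 2 for 1% of each. Among elements, none of 200 simulated changes was recovered (0 at either size), and of 1000 simulated rises of log2 5, 68.6% were recovered in Arabidopsis and 28.2% in Capsella. Simulated losses of 10 percentage points of CHH methylation were recovered in 7% of windows and losses of 40 points in 37.0% of 46 windows. Simulated losses of 35 points of CG were recovered in 25%, and losses of 20 points of CHG in 5%.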

Results

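The 32 samples fell into 16 groups defined by species, tissue, assay and genotype, and the nrpd1a against WT comparisons each set 2 libraries against 2, except the genome sequencing of 5 nrpd1a plants and 1 WT plant. Small RNA libraries held from 815700 reads (Arabidopsis microspores, nrpd1a replicate 1) to 6802012 reads (Capsella microspores, WT replicate 2). The number of distinct sequences ranged from 72002 in Capsella microspore nrpd1a replicate 1, where each was read 25.6 times on average, to 1249978 in Capsella microspore WT replicate 2, where each was read 5.44 times. The deposited RNA tables gave no read totals, so their absolute depth is unknown. Bisulfite libraries covered a listed cytosine 1.94 to 2.45 times on average, and 19.1% to 27.0% of cytosines were covered at least 4 times.

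The first comparison asked which small RNAs of Arabidopsis microspores depend on Pol IV. Small RNAs of 24 nt, the size that directs DNA methylation, made up 6.92% ± 1.25 of reads in nrpd1a and 24.6% ± 13.2 in WT (SD, n = 2). The 23-nt share was 6.89% ± 0.155 in nrpd1a and 11.9% ± 4.09 in WT, while 21-nt and 22-nt RNAs together held 19.8% ± 0.847 and 19.5% ± 5.84. Among 24-nt species, those starting with A were 37.1% ± 1.66 of distinct sequences in nrpd1a and 45.6% ± 2.80 in WT. Of 2811 sequences of 24 nt tested, 2377 fell and 113 rose in nrpd1a (edgeR), and 1134 had no read in either mutant library. Over sequences with at least 20 reads in a pair of libraries, chi-square per degree of freedom was 42.9 between the WT replicates. It was 12.3 between the nrpd1a replicates. Between genotypes it was 65.7 and 63.0 with WT replicate 1, and 33.8 and 37.3 with WT replicate 2. This value grows with read number, so pairs of unlike depth compare only loosely. The 24-nt sequence with the largest fall, CGCAAATCCTCTGGACGCAAATCC, had 383 WT reads and no nrpd1a read, and was at least 57.4-fold lower (adjusted p = 3.87e-05). The median log2 change of the 24-nt sequences was -5.31, or -3.49 with sequences without mutant reads at their bound. Of 1567 sequences of 21 and 22 nt, 392 fell and 255 rose, with the sequence AAGTGTAGAAGTCGAGATGCA at least 38.4-fold lower. Their median log2 change was 1.17, 540 had a negative change, and together they held 102041 reads per 1000000 (rpm) in nrpd1a and 41854 rpm in WT. Every share difference named for 23 and 24 nt separated the genotypes, with an exact permutation p = 0.333, the smallest possible, and the 24-nt difference was larger than the SD of either group. With TMM scaling 686 sequences of 24 nt fell and 16 rose, and of 21 and 22 nt 403 fell and 8 rose; scaled to known microRNAs 29 and 25 rose. With no filter on low counts no 24-nt sequence passed (0 in each direction in edgeR), while at 21 and 22 nt 5 rose and 142 fell. With every library drawn down to the smallest 953 of 1227 tested sequences of 24 nt fell, and of 954 tested at 21 and 22 nt 167 rose and 99 fell. Without WT replicate 1 or 2 the share difference in percentage points was -27.1 and -8.35 at 24 nt (-17.7 with all libraries), -7.90 and -2.11 at 23 nt (-5.01), and -3.88 and 4.38 at 21 and 22 nt (0.248; -0.351 and 0.847 without nrpd1a replicate 1 and 2, 11.8 within 20-nt to 25-nt reads, -1.24 by distinct sequences and 2.51 without the 10 most abundant sequences). Without WT replicate 2, 499 sequences of 24 nt fell; 38 and 43 rose without WT replicate 1 and 2, and for 21 and 22 nt the counts were 452 up and 257 down without WT replicate 1, 631 up and 220 down without WT replicate 2, and 0 in each direction without either nrpd1a library (edgeR).

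In Capsella microspores 24-nt RNAs held 5.86% ± 2.06 of reads in nrpd1a and 16.8% ± 0.165 in WT (SD, n = 2), and 23-nt RNAs 8.31% ± 2.28 and 17.8% ± 1.30. RNAs of 21 and 22 nt together held 23.9% ± 3.51 and 27.5% ± 1.14. Sequences starting with A, the kind loaded by AGO4-type Argonautes, were 54.8% ± 0.466 of distinct 24-nt sequences in WT and 29.2% ± 6.02 in nrpd1a. Of 8441 sequences of 24 nt tested, 7758 fell and 464 rose, and 6752 (80.0%) had no read in either nrpd1a library. The one with the largest fall, AAGAGATCTTCCAAACTGTTGGGG, went from 1860 WT reads to none and was at least 237-fold lower (adjusted p = 1.11e-10). Of 10482 sequences of 21 and 22 nt, 8417 fell and 1502 rose, and AAACGGACTCTCTCTACAGAGA was at least 148-fold lower. Together the tested sequences of 21 and 22 nt held 204715 rpm in nrpd1a and 125813 rpm in WT. Of them 6934 had no read in either nrpd1a library and 44 had none in either WT library. Most thus passed the filter through the deeper WT libraries, which favours falls in advance, as at 24 nt. The median log2 change was -6.81 at 24 nt and -6.40 at 21 and 22 nt, or -2.59 and -2.25 with sequences without mutant reads at their bound. Reads that lie inside the 5.8S ribosomal RNA held 7.74% and 7.08% of the nrpd1a libraries and 1.76% and 1.67% of the WT libraries. Chi-square per degree of freedom, taken as in Arabidopsis, was 80.0 between the nrpd1a replicates and 6.04 between the WT replicates. Between genotypes it was 113 to 135. The size-class differences had an exact permutation p = 0.333, the smallest possible, and when only 20-nt to 25-nt reads formed the total, the 21-nt and 22-nt share was 42.7% in nrpd1a and 35.0% in WT. The difference of that share over all reads, -3.55 percentage points, was -1.07 and -6.04 without nrpd1a replicate 1 and 2, -10.2 by distinct sequences and -6.39 without the 10 most abundant sequences. With every library drawn down to the smallest, 2576 of 3125 tested sequences of 24 nt fell and 301 rose, and 2062 of 3831 tested at 21 and 22 nt fell; with no filter on low counts the rises were 854 and 2625. Scaled to the known microRNAs, 1881 sequences of 24 nt fell and 688 rose, while 849 of 21 and 22 nt fell and 1987 rose; without WT replicate 1 or 2, 609 and 825 of 24 nt fell with 8 and 5 rises, and 266 and 323 of 21 and 22 nt fell with 115 and 106 rises.

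In Capsella leaves 24-nt RNAs held 7.00% ± 0.378 of reads in nrpd1a and 16.8% ± 2.36 in WT (SD, n = 2), and 23-nt RNAs 10.3% ± 0.429 and 14.7% ± 0.454. RNAs of 21 and 22 nt held more in nrpd1a, 38.4% ± 0.0897 against 32.7% ± 0.0451. Among distinct 24-nt sequences, 32.3% ± 0.0304 started with A in nrpd1a and 53.2% ± 1.38 in WT. Of 4191 sequences of 24 nt, 3027 fell and 131 rose, and 2772 had no read in nrpd1a; AAATTTTAGATCTGTACAACTTAC, with 1590 WT reads, was at least 525-fold lower. Of 5647 sequences of 21 and 22 nt, 1218 fell, led by TGATGATCTAGATGTACCTTAT at a fold of at least 516, and 1175 rose. The median log2 change was -6.91 at 24 nt, or -3.39 with bounds, and 0.44 at 21 and 22 nt. The exact permutation p of the shares was 0.333, the smallest possible. The 21-nt and 22-nt difference of 5.75 percentage points was 11.0 within 20-nt to 25-nt reads, and by distinct sequences those of 23 and 24 nt, -4.37 and -9.82, were -10.8 and -17.1. With no filter on low counts 6357 sequences of 24 nt fell, and 2041 of 21 and 22 nt rose and 2883 fell. With every library drawn down to the smallest 1262 of 2126 tested at 24 nt fell, and 703 of 3787 tested at 21 and 22 nt rose and 484 fell. With TMM scaling 1291 sequences of 21 and 22 nt fell and 784 rose, 240 of 24 nt rose, and 762 of 21 and 22 nt rose when scaled to known microRNAs, and without WT replicate 1 the rises were 766 at 21 and 22 nt and 83 at 24 nt.

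**Figure D1:**
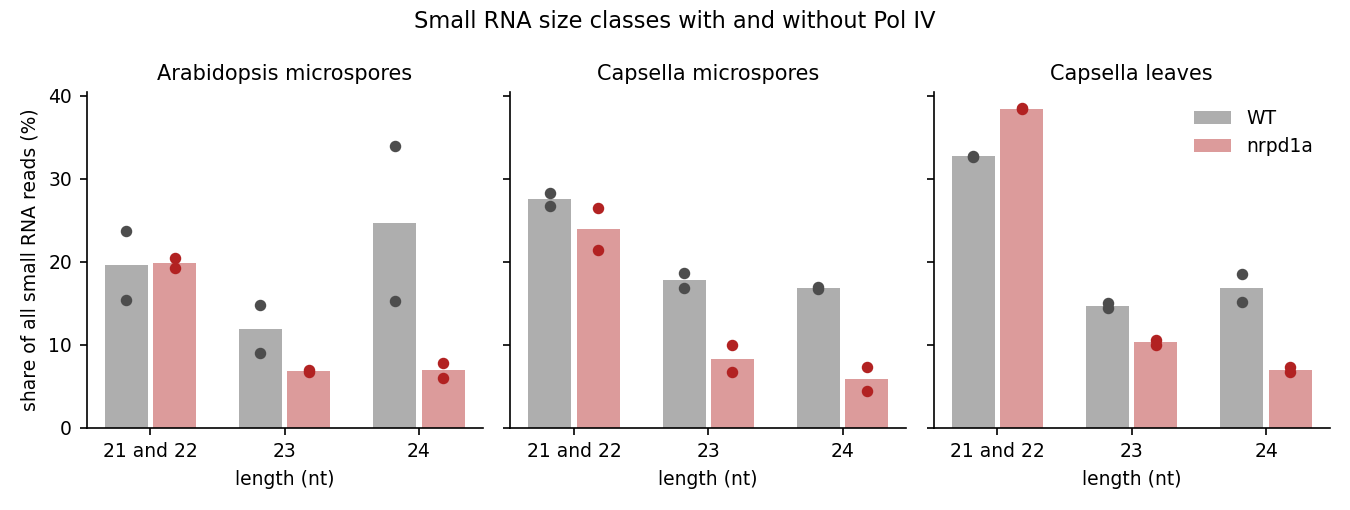
Share of all small RNA reads in percent (vertical axis) by length in nt (horizontal axis) for Arabidopsis microspores, Capsella microspores and Capsella leaves; points are libraries (n = 2 per group) and bars are means. The 24-nt share was 6.92% against 24.6%, 5.86% against 16.8% and 7.00% against 16.8% in nrpd1a against WT.

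Whether a sequence responded differently in Capsella microspores and leaves was tested as the interaction of genotype and tissue. At 24 nt, 442 of 11734 sequences had a more negative change in microspores and 477 in leaves. At 21 and 22 nt, 1303 of 14137 had a more negative change in microspores and 1211 in leaves. With TMM scaling 542 sequences of 24 nt and 1652 of 21 and 22 nt were more negative in microspores, and 317 and 759 in leaves. Among sequences with at least 20 WT reads in each tissue, 1201 of 24 nt and 1982 of 21 and 22 nt, the counts were 108 and 391 for microspores and 172 and 441 for leaves. Their median log2 change was -6.50 in leaves and -5.68 in microspores at 24 nt, and 0.43 and -0.32 at 21 and 22 nt. Over all tested sequences the leaf median was 0 at either size, against -6.22 (24 nt) and -5.79 (21 and 22 nt) in microspores. The counts over all sequences therefore also reflect in which tissue a sequence was read.

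Conserved microRNAs are made by DCL1 without Pol IV. In Capsella microspores 16 of 17 known mature sequences were lower in nrpd1a (17 of 17 with TMM scaling), and 12 fell (adjusted over the list alone). The largest fall was that of miR173, the trigger of TAS1 and TAS2 siRNAs, at a log2 change of -5.18 ± 0.99 (SE), from 25.6 to 0.621 rpm. miR168a, which controls AGO1, fell by 3.80, miR162a, which controls DCL1, fell by 3.53 from 1187 rpm, miR398a fell by 3.56 and miR167a fell by 3.37. The TAS3 siRNA tasiR-ARF D7 fell by 3.02 and miR403, which targets AGO2, fell by 2.63. miR172a fell by 2.68, miR395a by 2.09, miR160a by 1.94, miR396b by 1.91 and miR390a by 1.70, while miR159b, which targets GAMYB genes in anthers, had a log2 change of 0.42 and miR159a of -0.91. In Arabidopsis microspores 20 of 21 known sequences were higher in nrpd1a, but 14 of 21 were lower with TMM scaling, and no sequence passed the threshold over the list alone (0 in edgeR, 5 at an unadjusted p under 0.05; no other tool was run on the list). Adjusted over all 21-nt and 22-nt sequences instead, miR162a and miR165a rose there (adjusted p = 0.0224 and 0.0405), with changes of 0.42 and -0.02 and no call under TMM scaling. Values were 2.19 for miR162a, 1.73 for miR165a, 2.27 for miR173 and -2.47 for miR845b, a pollen microRNA that targets retrotransposons. In Capsella leaves 12 of 21 were higher, but 15 of 21 were lower with TMM scaling. There miR398a fell by 1.67, miR395a by 1.58, miR164a by 1.39 and miR167a by 1.34, and miR393a rose by 1.70 (adjusted over the list alone), and miR157a (-0.89) passed over all sequences only (adjusted p = 0.0417). The difference between tissues and species was not tested for these sequences. Arabidopsis microspore libraries held 1 or 0 reads inside the 5.8S ribosomal RNA, so the read totals used for scaling are unlike between the species. In the Capsella microspore libraries reads of 18 nt held 24.9% and 17.8% in nrpd1a and 8.85% and 9.50% in WT, reads of 19 nt 20.9% and 17.4% against 9.74% and 10.1%, and 5.8S reads 7.74% and 7.08% against 1.76% and 1.67%.

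**Figure D2:**
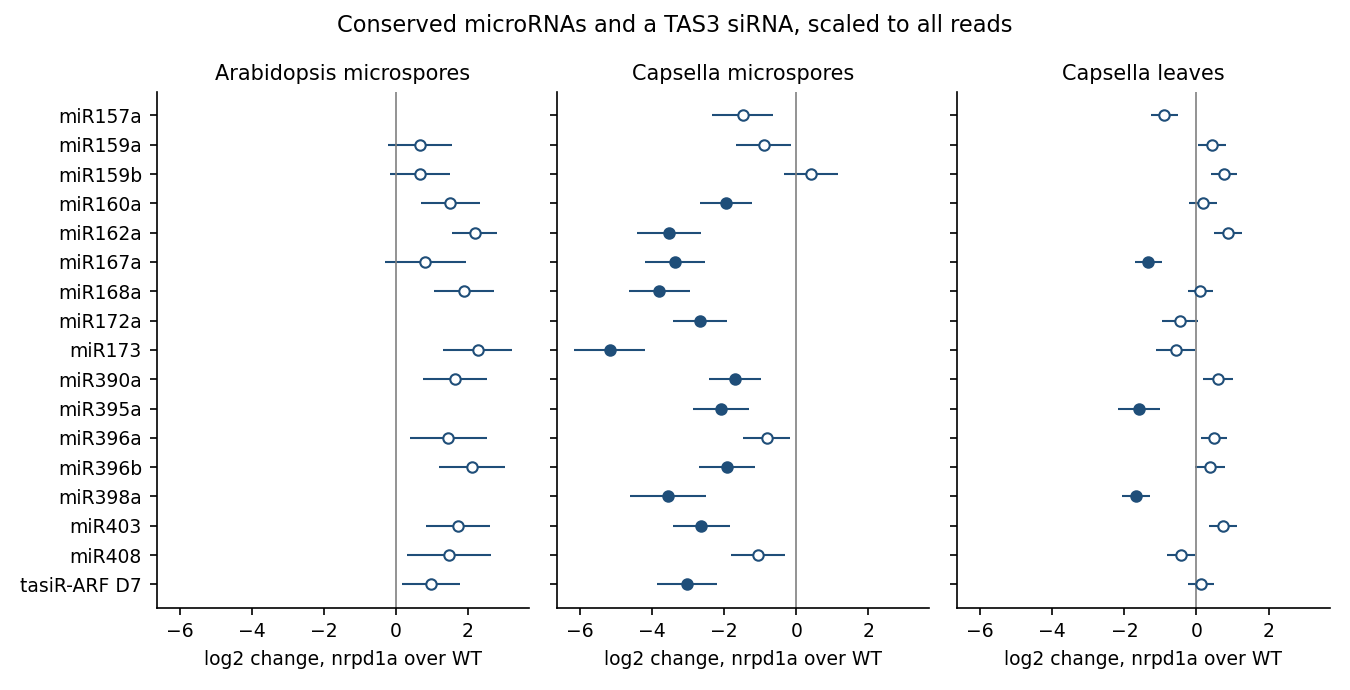
Log2 change in nrpd1a over WT (horizontal axis, error bars 1 SE, n = 2 per group) of the conserved microRNAs and the TAS3 siRNA tested in Capsella microspores, shown in each tissue where they could be tested. Filled points passed the threshold over the list alone; miR173 lay at -5.18 in Capsella microspores and at 2.27 in Arabidopsis microspores, where 14 of 21 sequences turned out lower with TMM scaling.

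In Arabidopsis microspores the RNA comparison asked which genes change without Pol IV. Genes of photosynthesis, normally a leaf programme, were higher as a list with camera of limma (adjusted p = 1.67e-06), but not with an estimated correlation (adjusted p = 0.534). Of 13 tested, 6 rose and 12 were higher, also with cyclic loess, quantile normalization or equal medians. PSBO1, of the oxygen-evolving complex, rose from 15.1 ± 0.275 to 93.3 ± 9.63 RPKM (SD, n = 2; log2 change 2.55 ± 0.18 SE; adjusted p = 0.0131). The light-harvesting genes CAB2, LHCB1.4 and LHCA1 rose by 2.55, 2.42 and 2.29, and the Rubisco small subunit genes RBCS1B and RBCS3B rose by 2.57 and 1.96, while PSAD1 had a log2 change of -0.40. Adjusted over the list alone 9 rose, adding CAB3 (1.71), RCA (1.21) and RBCS2B (1.65). Pollen maturation genes were higher in 17 of 17 cases, and in 16 of 17 under each of those scalings, with a median log2 change of 0.64. The pectin methylesterase PPME1 (2.06, from 53.5 ± 25.2 to 220 ± 74.2 RPKM) and the MADS gene AGL104 (1.02) rose adjusted over the list alone, and VGDH1 (1.93) and ACT12 (1.04) did not pass. Of 16 cell cycle genes 12 were higher (11, 11 and 10 under those scalings), and 5 rose adjusted over the list alone. These were the mitotic cyclins CYCB1;1 (1.02) and CYCB1;2 (0.98), CDC20.1 (1.07) and CDC20.2 (1.26) of the anaphase-promoting complex and the kinase AUR1 (0.84).

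Components of RNA-directed DNA methylation did not pass the threshold (0 of 23 over all genes or over the list alone in limma, 5 at an unadjusted p under 0.05), and 16 of 23 were lower (17 with cyclic loess, 18 with quantile normalization, 17 with equal medians). NRPD1 itself, the mutated gene, was read at 3.30 ± 0.795 RPKM in nrpd1a and 3.32 ± 0.641 in WT, so these values do not tell the genotypes apart. IDN2 and RDM1 had values of -0.90 and -0.71, and DCL3, the Dicer that makes 24-nt siRNAs, of 0.89. ROS1, the glycosylase that removes DNA methylation, fell by 1.18 adjusted over the list alone, and MOM1 (-0.63), DML3 (-0.73) and SUVH4 (-0.36) did not pass. In the tapetum list LAP6, a pollen wall polyketide synthase, rose by 2.13 (0.921 to 7.30 RPKM), with ACOS5 (1.65), GRP19 (2.51) and GRP17 (-1.35) not passing. COR15A, a cold-response gene, rose by 1.36 adjusted over the list alone. RD29A (-0.82), HSP18.2 (0.64) and HSP70-4 (0.56) did not pass. The meiosis genes SDS (0.77), SWI1 (-0.91), ASY1 (0.57) and TAM (0.40), the germline genes MGH3 (0.65), GEM1 (0.27), DMP9 (-0.31) and SCP (0.28), and the silencing genes DCL4 (0.60), AGO1 (0.97), DCL1 (-0.41) and RDR6 (0.32) did not pass either.

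Over all 18907 Arabidopsis genes tested, 318 rose and 36 fell (limma), with AT1G15405 (6.97) and AT4G02970 (5.64) the largest rises and AT4G18720 (-2.07) and AT2G16310 (-2.06) the largest falls. Set tests called photosynthesis (adjusted p = 1.67e-06), pollen maturation (adjusted p = 0.0207) and cell cycle (adjusted p = 0.0295) as higher relative to the other genes. None of these 3 calls held with an estimated correlation (adjusted p = 0.534, 0.716 and 0.534). The other lists did not pass: RNA-directed DNA methylation gave an adjusted p of 0.206, methylation maintenance and demethylation 0.231, defence and stress 0.528, tapetum, meiosis and post-transcriptional silencing 0.7096 each, and microspore division 0.793. Of the genes called, 89.8% rose, and 79.0% with quantile normalization or 59.0% with the medians of all genes set equal. With no filter on low RPKM no gene passed (0 in each direction in limma), the falls were 15 with a pseudocount of 0.1, and without the mean-variance trend 182 rose and 8 fell. Without either nrpd1a library no gene was called (0 in each direction in limma), without WT replicate 1 or 2 there were 1182 and 1450 rises and 529 and 534 falls, pollen maturation was lost without WT replicate 2 (adjusted p = 0.558) or nrpd1a replicate 1 (adjusted p = 0.155), and cell cycle without WT replicate 1 (adjusted p = 0.244) or nrpd1a replicate 2 (adjusted p = 0.0914).

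**Figure D3:**
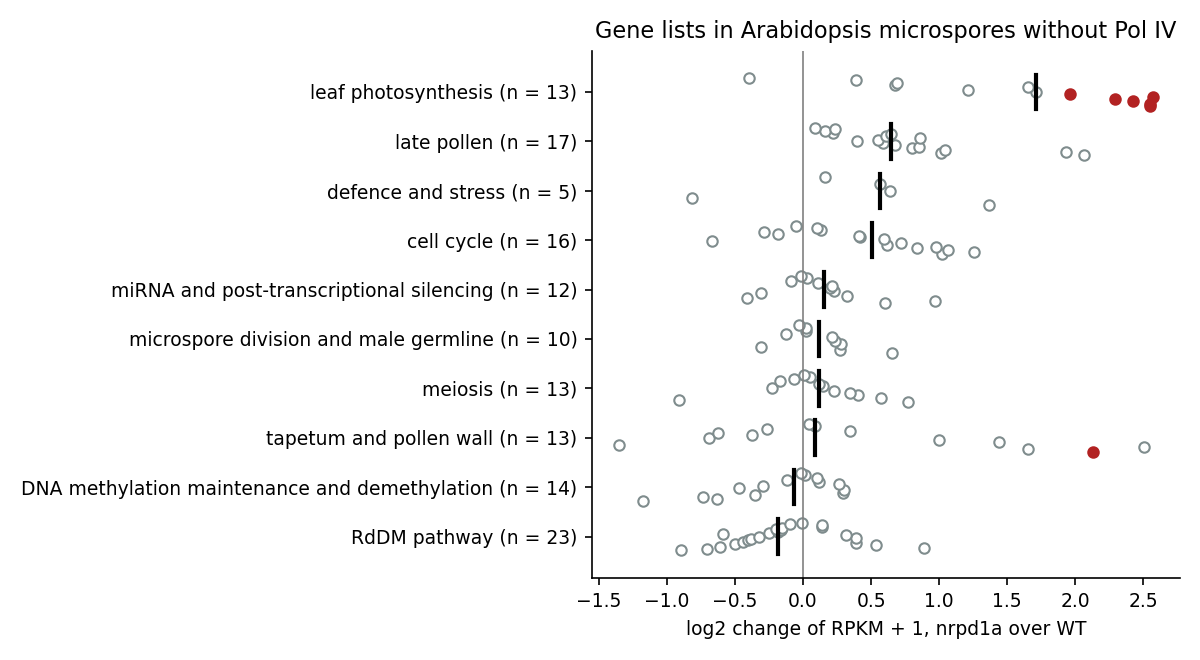
Log2 change of RPKM + 1 in nrpd1a over WT (horizontal axis) for each tested member of the 10 gene lists in Arabidopsis microspores (n = 2 libraries per group); black bars are list medians, and filled points passed the threshold over all genes. The photosynthesis median was 1.71, and 6 of its 13 members passed.

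In Capsella microspores, of 18938 genes tested, 2973 rose and 730 fell in nrpd1a (limma). Among them 545 genes were below 1 RPKM in both WT libraries and rose, 106 of these from values listed at 0, against 41 and 5 in Arabidopsis; the difference between the species was not tested, because the files do not pair their genes. Carubv10028651m.g.v1.0, listed at 0 in both WT libraries, reached 91.7 ± 29.6 RPKM in nrpd1a (SD, n = 2; adjusted p = 6.35e-06), and Carubv10000839m.g.v1.0 rose from 0.753 ± 0.524 to 61.1 ± 36.0 RPKM (log2 change 5.05 ± 0.46 SE). Carubv10011450m.g.v1.0 fell from 149 ± 11.1 to 15.8 ± 17.7 RPKM (log2 change -3.74 ± 0.62) and Carubv10015920m.g.v1.0 from 43.2 ± 10.8 to 5.72 ± 7.05 (log2 change -3.27 ± 0.64). The files do not pair these identifiers with names. The median of all genes lay at a log2 change of 0.38, and the share of rises among called genes, 80.3% as deposited, was 53.5% with cyclic loess (1057 up, 919 down), 57.7% with quantile normalization (983 up, 721 down) and 47.7% with the medians set equal (876 up, 960 down). With no filter on low RPKM 1540 rose and 303 fell. Without WT replicate 1, WT replicate 2 or nrpd1a replicate 2 no gene was called (0 in each direction in limma), and without nrpd1a replicate 1 there were 428 rises and 331 falls.

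Annotated transposable elements, the usual targets of Pol IV, were tested in the same RNA. In Capsella microspores 1509 of 9581 elements rose and 547 fell, with a median log2 change of 0.63. Of the tested elements 1784 were at 0 in both WT libraries and 536 at 0 in both nrpd1a libraries. Element reads, estimated from the smallest values, were 1.42 times those of WT replicate 1 in WT replicate 2. In nrpd1a they were 1.74 and 1.77 times those of WT replicate 1. Fewer element reads in WT make zeros more likely there, so the counts at 0 are not matched for depth. The minimum of 1 RPKM left out few elements, since 7415 of 7442 above 0 in WT replicate 1 reached it. Values near the floor therefore weigh on these changes. Replicates correlated at r = 0.671 in WT and 0.515 in nrpd1a. In Arabidopsis none of 5406 elements passed in either direction (0 in limma, with 1160 at an unadjusted p under 0.05; no other tool was run on RPKM), at the same median of 0.63. The elements as a list were higher than genes in Arabidopsis (camera of limma, adjusted p = 0.000140 for this 1 list, and 0.227 with an estimated correlation). In Capsella camera pointed down (adjusted p = 0.537 for this 1 list) although the median of elements exceeded that of genes, and up on the denominator of the genes (adjusted p = 0.530). On the denominator of the genes the element medians were 0.41 in Arabidopsis and 0.98 in Capsella, and element reads per gene read in nrpd1a over WT were 0.826 and 1.36. With cyclic loess the medians were -0.28 and -0.22, with quantile normalization -0.24 and -0.06, and under these scalings, and with no filter on low RPKM, no Capsella element passed (0 in each direction in limma). Without either WT library no Capsella element passed, without nrpd1a replicate 2 the falls were 94, and in Arabidopsis 557 elements rose and 88 fell with a pseudocount of 0.1, and 521 and 544 elements rose without nrpd1a replicate 1 and 2.

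DNA methylation in Capsella leaves was compared to see which contexts depend on Pol IV. CHH methylation, a context kept up in part by siRNA-directed methylation, was 1.01% ± 0.0431 in nrpd1a and 1.21% ± 0.00598 in WT (SD, n = 2), a relative change of -16.3%. CHG methylation was 3.10% ± 0.0271 and 3.49% ± 0.211, and CG methylation differed by 0.219 percentage points (SD 0.457 and 0.375). Windows of 300 bp with at least 10 reads in each context and library, whatever the coverage of single cytosines, were grouped by the CHG level of 1 WT library, and nrpd1a was compared with the other WT library. Grouped by WT replicate 1 and 2, the relative change of CHH methylation was -0.518% and 1.12% in windows below 5% CHG, -29.1% and -25.2% in those of 5% to 20%, -21.5% and -16.1% in those of 20% to 40%, and -24.3% and -19.4% above 40%. In 14070 windows of 5% to 20% by WT replicate 1, CHH methylation was 1.92% ± 0.0212 in nrpd1a (SD, n = 2) and 2.70% in WT replicate 2, and the relative change of CHG methylation was -16.8%. With 1 WT library on each side these changes, and their difference between groups of windows, were not tested. Grouping by WT picks windows methylated in WT, which favours losses in the upper groups. Below 5% the relative change of CHG methylation was 11.6% and 12.0%. Grouped by the mean CHG level of all libraries, the CHH changes were -0.576%, -41.2%, -20.1% and -3.48% from the lowest to the highest group. There the compared libraries set the groups themselves. Over all reads, where the relative change of CHH methylation was -20.0%, it was by trinucleotide -41.1% at CCC, -31.7% at CCA and -29.1% at CCT, and -11.9% at CAA. On each of scaffolds 1 to 8 the CHH level over all reads was lower in nrpd1a, by a relative change between -17.8% and -22.5%. CHH and CHG levels separated the genotypes (exact permutation p = 0.333, the smallest possible), and CG levels did not (exact permutation p = 0.667). With cytosines covered at least 10 times the difference turned, to 0.443 percentage points for CHH and 1.32 for CHG, and was 3.30 for CG. Without WT replicate 1 the CHG difference was -0.242 (-0.391 with all libraries) and the CG difference -0.0459, and the CG difference was 0.484 without WT replicate 2, and 0.542 and -0.104 without nrpd1a replicate 1 and 2.

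**Figure D4:**
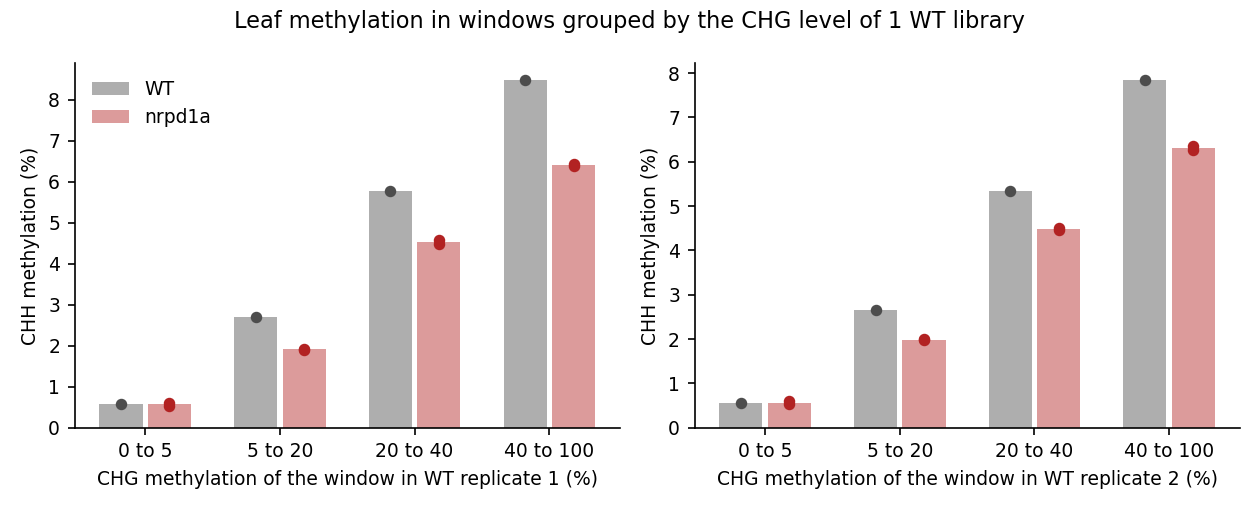
CHH methylation in percent (vertical axes) of Capsella leaves in windows grouped by the CHG level of 1 WT library over all reads in percent (horizontal axes), WT replicate 1 on the left and WT replicate 2 on the right. Points are the 2 nrpd1a libraries and the other WT library, and bars are means. In windows of 5% to 20% CHG the relative change was -29.1% and -25.2%.

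Window by window, 313 of 202633 tested windows lost CHH methylation in nrpd1a and none gained it (0 in edgeR, with 27 at an unadjusted p under 0.05 and the minimum difference, and 28 by Fisher's exact test). In the CHG context 12 of 27011 tested windows lost methylation and none gained it (0 in edgeR, 14 at an unadjusted p under 0.05 and the minimum difference, and 15 by Fisher's exact test). In the CG context 8 of 17718 tested windows gained and 6 lost methylation. With the windows left out for want of methylated or unmethylated reads, there were 226147 CHH, 38755 CHG and 23741 CG windows. The CHH window at 9079501 to 9079800 on scaffold 8 went from 53.8% ± 14.9 in WT to 0% in nrpd1a (SD, n = 2; 109 and 104 reads; adjusted p = 0.00244), and the one at 12468001 to 12468300 on scaffold 7 from 65.2% ± 37.0 to 0%. The CHG window at 6043501 to 6043800 on scaffold 4 went from 69.3% ± 10.4 to 0% (51 and 75 reads; adjusted p = 0.00160). The CG window at 628801 to 629100 on scaffold 8 went from 4.42% ± 2.88 to 77.1% ± 12.1 (adjusted p = 0.00191), and the CG window at 14973601 to 14973900 on scaffold 7 from 59.7% ± 3.18 to 0%. The files name no genes at these windows. No CG window gained methylation with windows of 1000 bp (0 in edgeR, with 277 changed at an unadjusted p under 0.05 and the minimum difference) or at a coverage of 10 (0 in each direction in edgeR, and none at an unadjusted p under 0.05 with the minimum difference). By Fisher's exact test, over the same cytosines and over all reads, 71, 4 and 64 CG windows gained and 29, 6 and 88 lost, the CHG losses were 101, 19 and 110, and the CHH losses 1592, 108 and 2224. At a coverage of 10 the CHG and CHH losses were 3 and 18. With no minimum difference 35 CG, 6 CHG and 3 CHH windows gained, 1 CHG window gained with 1000 bp, and over all reads 3 CHG windows and 1 CHH window gained. Without nrpd1a replicate 1 or 2 the CHH losses were 23 and 25, the CHG losses 3 and 0 (edgeR), the CG gains 4 each and the CG losses 1 each. Without WT replicate 1 or 2 the CHG losses were 3 and 5, the CG gains 2 and 4 and the CG losses 3 and 2.

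The genome sequencing of Capsella leaves asked whether elements insert anew without Pol IV. The table listed 1079 positions, of which 759 (70.3%) were in 1 plant alone and 42 in every plant. The WT plant had 282 listed insertions, and the 5 nrpd1a plants had 433, 287, 254, 296 and 251, a mean of 304.2 ± 74.7 (SD), with 3 of 5 above WT (exact permutation p = 0.667; the smallest possible is 0.167). Insertions listed in that plant alone were 107 in WT and 249, 112, 91, 117 and 83 in nrpd1a, a mean of 130.4 ± 67.8 (exact permutation p = 0.667). This count is not alike for the genotypes, since nrpd1a plants can share insertions with each other and the WT plant had no other WT plant. Over the 5 nrpd1a plants 797 positions were listed that were not in WT, 142 of them in 2 to 4 nrpd1a plants. Insertions shared by nrpd1a plants are therefore left out of their counts. The element te16007 was listed at 39 positions, 10 in the WT plant and a mean of 10 in nrpd1a plants, te94516 at 35 (9 and a mean of 9.4) and te16009 at 30 (8 and a mean of 7.2). In all, 129 of 574 elements were listed at 3 positions or more. Of the elements inserted in 1 nrpd1a plant alone, 79 had microspore RNA values and 13 of these rose (16.5%, against 15.7% of the other elements, Fisher's exact p = 0.877). Their median log2 change was 2.36, against 0.63 for all tested elements. For the 20 elements with RNA values inserted in the WT plant alone it was 1.78. These medians were not tested, and the elements were taken from positions before merging. Without plant 1, as numbered in the table, the nrpd1a mean was 272, and the differences from WT were -10 for all insertions and -6.25 for those in that plant alone. When positions within 100 bp that share an element were taken as 1, the insertions in that plant alone were 36 in WT and 149, 35, 23, 46 and 25 in nrpd1a. Of the 678 positions left after merging, 314 were in 1 plant alone and 115 in every plant.

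**Figure D5:**
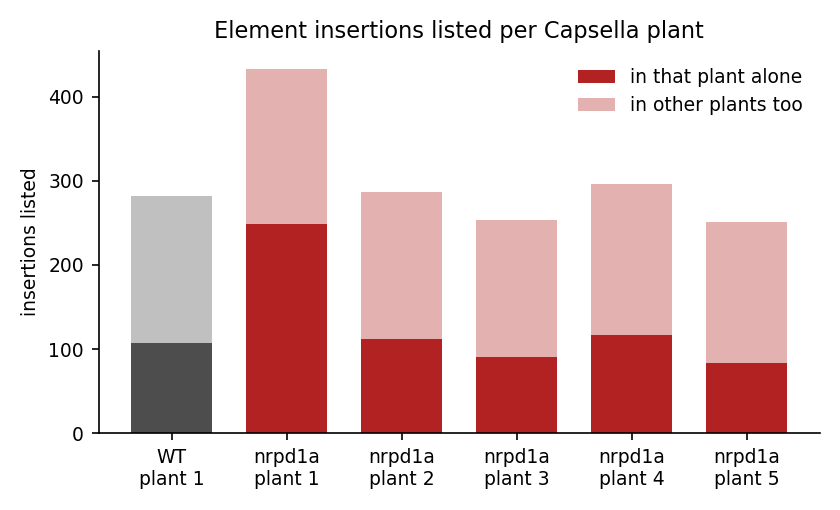
Number of element insertions listed per Capsella plant (vertical axis) for the WT plant and the 5 nrpd1a plants (horizontal axis); dark parts are insertions listed in that plant alone, pale parts those listed in other plants too. The WT plant had 282, and nrpd1a plants had 251 to 433.

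Arabidopsis pollen of rdr2, which lacks the polymerase that makes Pol IV transcripts double-stranded, and of rdr6, which lacks the one acting on TAS and other transcripts, had 1 library each. In rdr2 24-nt RNAs held 11.3% of 1466076 reads (95% Clopper-Pearson interval 11.2% to 11.3%), and in rdr6 13.9% of 6627080 reads (13.9% to 13.9%). RNAs of 21 and 22 nt held 27.5% in rdr2 (27.4% to 27.6%) and 25.8% in rdr6 (25.8% to 25.9%). With 1 library per genotype and no WT pollen, the difference was not tested. The labels name rdr2 and rdr6 as title and source but Col-0 as genotype, and the values stand for these mutants only if the titles hold. Within reads of 20 to 25 nt the 24-nt share was 15.1% in rdr2 and 18.5% in rdr6. By distinct sequences it was 10.8% and 24.5%, and of the distinct 24-nt sequences 29.8% started with A in rdr2 (28.9% to 30.7%) and 42.3% in rdr6 (41.9% to 42.6%).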

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

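The tests on read number, on other RNA in the libraries and on leaf microRNAs below were chosen after the falls in Capsella microspores were seen, as were the merging of insertion positions and the scaling to known microRNAs.

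Among the 5 nrpd1a Capsella plants, plant 1 lay far from the others by Dixon's test, with 433 insertions listed (others 251 to 296; ratio 0.753, critical value 0.71) and 249 listed in that plant alone (others 83 to 117; ratio 0.795). It also stood apart with 149 merged positions in that plant alone (others 23 to 46; ratio 0.817). Its 367 distinct elements did not pass (ratio 0.662). Chance flags about 1 in 20 groups, and these 3 counts come from the same plants and are not separate evidence. The depth of the genomes was not given, so no technical or biological explanation was tested.

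The genotype effect differed between Capsella microspores and leaves for single sequences in a test of the interaction. At 21 and 22 nt 1303 sequences had a more negative change in microspores and 1211 in leaves, and at 24 nt 442 and 477. Only 1982 of 14137 sequences of 21 and 22 nt and 1201 of 11734 of 24 nt had at least 20 WT reads in each tissue. Among these the counts were 391 and 441, and 108 and 172. The counts over all sequences therefore also reflect in which tissue a sequence was read. The share of 21-nt and 22-nt reads was 5.75 percentage points higher in nrpd1a leaves and changed by -3.55 points in nrpd1a microspores, with the libraries of each tissue moving in opposite ways over all reads; this difference between tissues was not tested. Within 20-nt to 25-nt reads the difference was 11.0 points in leaves and 7.72 in microspores, so both moved the same way. Of 13 known small RNAs tested in microspores of each species, 8 were above WT in both Arabidopsis nrpd1a libraries and below WT in both Capsella ones: miR160a, miR162a, miR168a, miR173, miR390a, miR396b, miR403 and tasiR-ARF D7. That difference between species was not tested either, and it rests in part on the total of reads as library size. These totals were unlike between the species. Arabidopsis microspore libraries held 1 or 0 reads inside the 5.8S ribosomal RNA and spanned 13 to 46 nt. Capsella microspore libraries held 1.67% to 7.74% such reads and spanned 16 to 30 nt. With TMM scaling miR160a (-0.22), miR390a (-0.0793) and tasiR-ARF D7 (-0.77) were lower in Arabidopsis, as were 14 of all 21 sequences there. miR162a (0.42), miR168a (0.11), miR173 (0.64), miR396b (0.44) and miR403 (0.10) stayed higher, with no call.

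The pattern weighed was the fall of 24-nt sequences and of known microRNAs in Capsella microspores without Pol IV. Fewer reads in nrpd1a were argued against for the 24-nt sequences. With every library drawn down to the smallest, 2576 of the 3125 sequences that could then be tested fell (82.4%), against 7758 of 8441 before. Drawing down evens out read totals, not the number of distinct molecules sampled. In nrpd1a replicate 1 each distinct sequence was read 25.6 times on average, against 7.79 in nrpd1a replicate 2 and 4.58 and 5.44 in WT. Few distinct molecules in that library therefore stay open as a part of the fall. Other RNA lowering every small RNA alike could not be decided for the 24-nt sequences. With libraries scaled to known microRNAs 2.73 sequences of 24 nt fell for each that rose, while at 21 and 22 nt 849 fell and 1987 rose. This scaling cannot decide the question, because the known sequences tested held 1795 rpm in WT and 258 rpm in nrpd1a. Most of the WT amount was miR162a, which itself fell, so the scaling largely undoes the fall of few sequences. Most tested 24-nt sequences passed the filter through the WT libraries, which favours falls in advance. Of the 8441, 6752 had no nrpd1a read and 11 had no WT read. For the microRNAs themselves that explanation cannot be told apart, because their spread over its degrees of freedom, 2.70, lay between the bounds of 1.5 and 3, and 5.8S reads were higher in the nrpd1a libraries (7.74% and 7.08% against 1.76% and 1.67%), as were reads of 18 nt (24.9% and 17.8% against 8.85% and 9.50%), so that broken RNA stays open as a part of it. A need of the microRNAs as a set for Pol IV in every tissue was argued against by a median log2 change of 0.12 in leaves. With TMM scaling the leaf median was -0.36, and 15 of 21 were lower. As miR167a, miR395a and miR398a fell in both tissues over the list alone, a need of single microRNAs stays open. A need in microspores alone and a difference in the cells collected stay open as untested.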

How the results depend on the processing

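Chosen after seeing the data were scaling to known microRNAs, drawing libraries down to the smallest, shares and levels within replicate numbers, 20 WT reads per tissue, equal medians, the gene denominator, cytosines covered in every library or all reads, and merged insertions. The causes of the changes below were not tested. Depth limits what was covered: at most 27.0% of cytosines were covered 4 times. Among single genes, sequences and sites, 972 values kept direction and side of the threshold, 83 passed it newly, 157 no longer passed and 37 turned.

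With distinct sequences the Arabidopsis 21-nt and 22-nt share difference was -1.24, and leaving out libraries gave -3.88 to 4.38. With 20-nt to 25-nt reads the Capsella microspore difference was 7.72, and pollen shares of 21 and 22 nt were 36.8 (rdr2) and 34.4 (rdr6), of 24 nt 15.1 and 18.5; without the 10 most abundant sequences they were 27.0, 24.9, 11.6 and 14.3.

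Log2 changes turned with TMM in Arabidopsis for miR159a (-0.96), miR159b (-0.98), miR160a (-0.22), miR161.1 (-1.09), miR165a (-0.0192), miR166a (-0.33), miR167a (-0.74), miR319a (-1.74; -0.12 with the smallest library), miR390a (-0.0793), miR396a (-0.40), miR408 (-0.13), miR845a (-1.15) and tasiR-ARF D7 (-0.77), in Capsella microspores for miR159b (-0.59), and in leaves for miR159a (-0.0531), miR160a (-0.30), miR168a (-0.38), miR396b (-0.11), miR399b (-0.0237) and tasiR-ARF D7 (-0.36). Leaving out libraries gave, in Arabidopsis, -0.11 to 2.51 (miR159a), -0.0931 to 2.34 (miR159b), -0.0723 to 1.89 (miR161.1), -0.0992 to 3.93 (miR167a), -0.0492 to 0.12 (miR319a), -0.11 to 6.69 (miR408) and -0.0427 to 0.60 (SCP RNA), in Capsella microspores -0.0664 to 0.78 (miR159b), and in leaves -0.0535 to 1.18 (miR159a), -0.44 to 0.63 (miR160a), -0.20 to 0.52 (miR168a) and -0.15 to 0.35 (tasiR-ARF D7).

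Rises and falls of sequences changed as follows. TMM: Arabidopsis 8 and 16 rose (21 and 22 nt, 24 nt), 686 of 24 nt fell, 240 of 24 nt rose in leaves, and 759 and 317 were more negative in leaves. Known-microRNA scaling: Arabidopsis 25 and 29 rose, Capsella microspore 849 and 1881 fell, leaf 762 of 21 and 22 nt rose. No filter: Arabidopsis 5 rose and 142 fell at 21 and 22 nt, 0 and 0 at 24 nt (edgeR), Capsella microspore 2625 and 854 rose, leaf 2041 rose and 2883 fell at 21 and 22 nt, 6357 fell at 24 nt. Smallest library: Arabidopsis 167 rose and 99 fell at 21 and 22 nt, 953 fell at 24 nt, Capsella microspore 301 of 24 nt rose, 2062 and 2576 fell, leaf 703 rose and 484 fell at 21 and 22 nt, 1262 fell at 24 nt. With 20 WT reads per tissue 391 and 108 were more negative in microspores, 441 and 172 in leaves. With replicate numbers as pairs, which the labels do not state, Arabidopsis 68 and 67 rose and 182 of 21 and 22 nt fell, and Capsella microspore 716 and 158 rose, 1274 and 2433 fell. Leaving out 1 library, with the lone sample assumed to vary like the other groups: Arabidopsis 21 and 22 nt 0 to 631 rose, 0 to 257 fell, 24 nt 38 to 158 rose, 499 to 2353 fell; Capsella microspore 21 and 22 nt 106 to 1660 rose, 266 to 8559 fell, 24 nt 5 to 520 rose, 609 to 7845 fell; leaf 766 to 1250 and 83 to 134 rose.

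RNA: without filter Arabidopsis 0 and 0, Capsella 1540 up and 303 down, Capsella elements 0 and 0. Without trend Arabidopsis 182 up and 8 down. Pseudocount 0.1: Arabidopsis 15 down, elements 557 up and 88 down. Quantile: Arabidopsis 121 down, elements 8 up, Capsella 983 up, elements 0 and 0. Loess: Capsella 1057 up, elements 0 and 0. Equal medians: Arabidopsis 249 down, Capsella 876 up. Pairs: Arabidopsis 1207 up and 491 down, Capsella elements 0 and 0. Leaving out: Arabidopsis 0 to 1450 up, 0 to 534 down, elements 0 to 544 up; Capsella 0 to 428 up, 0 to 331 down, elements 0 to 1838 up, 0 to 441 down. Set tests of photosynthesis, late pollen, cell cycle and Arabidopsis elements gave an adjusted p of 0.534, 0.716, 0.534 and 0.227 with an estimated correlation (elements on the gene denominator 0.466) and 0.110, 0.378, 0.110 and 0.0818 with fry, which tests a list against no change and not against other genes; pairs gave 0.0574 for cell cycle, and leaving out 5.19e-06 to 0.558 for late pollen, 0.0276 to 0.244 for cell cycle, 0.498 to 0.966 for meiosis and 0.526 to 0.966 for microspore division, whose directions turned. Capsella elements pointed up on the gene denominator (0.530, or 0.287 with an estimated correlation).

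Methylation: at coverage 10 the level difference was 1.32 (CHG) and 0.443 (CHH), and 0.152 (CHG) over cytosines covered 10 times in every library; leaving out gave -0.104 to 0.542 for CG. Windows: no minimum difference, CG 35, CHG 6, CHH 3 gained; Fisher's exact test, CG 71 gained and 29 lost, CHG 15 and 101, CHH 28 and 1592; coverage 10, CG 0 and 0 (edgeR), CHG 3 lost, CHH 18 lost; 1000 bp, CG 0 gained and 1 lost, CHG 1 gained; same cytosines, CG 4 gained, CHG 19 lost, CHH 108 lost; all reads, CG 64 and 88, CHG 3 and 110, CHH 1 and 2224; pairs, CHG 5 lost, CHH 53 lost. Leaving out: CG 2 to 4 gained, 1 to 3 lost; CHG 0 to 5 lost; CHH 0 to 1 gained, 23 to 280 lost.

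Insertions: leaving out 1 plant gave -10 to 35.5 for all and -6.25 to 35.25 for those in that plant alone; counting those not in WT gave 204.2 per nrpd1a plant. Pairing by replicate number leaves the mean share and level differences as they were, with an exact sign-flip p of at least 0.5, the smallest possible; only the Arabidopsis 21-nt and 22-nt share differed in sign between numbers (4.98 and -4.48). No paired analysis was possible because the insertions have 1 WT plant. Genome windows of small RNA, scaling to annotated microRNA loci, a read-support filter on insertions, the overlaps of siRNA with CHH and with RNA changes and the ortholog correlation were not run, because the files hold no positions, read support or names for them.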

Other observations

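The tests of dependence on 1 nrpd1a library and of background were chosen after the rise of Capsella genes was seen. An earlier test of the scaling, which set the medians equal, was dropped because it fixes its own outcome, and one of background on genes listed at 0 because the depth is not given.

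In Capsella leaves the 24-nt sequences that start with U were 31.5% ± 0.318 of distinct sequences in nrpd1a and 21.8% ± 0.497 in WT (SD, n = 2), and those starting with C 21.8% ± 0.182 and 11.8% ± 0.651. In Capsella microspores U-starting ones were 30.5% ± 2.82 and 19.0% ± 0.210. Over all reads of the CHG context the relative change of methylation in nrpd1a leaves was -15.8% at CCG, -8.77% at CAG and -9.39% at CTG.

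The pattern weighed was the rise of genes in Capsella microspores, whose median log2 change was 0.38, with 80.3% of the called genes rising. Dependence of the median on 1 nrpd1a library was argued against, since it was 0.45 without replicate 1 and 0.35 without replicate 2. For the called genes it cannot be told apart, because the share of rises was 56.4% without replicate 1 and no gene was called without replicate 2 (0 in limma). DNA or intergenic background was argued against as the whole cause of the median, since it adds the same RPKM at every level, while the median gain of the fourth of 5 equal groups of genes by level was at least 2.55 times that of the second in each pair of an nrpd1a and a WT library. As a part it stays open: elements above 0 were 13223 and 9172 in nrpd1a and 7442 and 7665 in WT, and element reads per gene read were 1.36 times those of WT. Scaling of the deposited values cannot be told apart from a broad rise, because the medians of the upper 3 groups differed by 0.21, between the bounds of 0.2 and 0.4 set for the test. The medians of the lower 2 groups were 0.55 and 0.51 and that of the top group 0.19, where 1 factor with a pseudocount of 1 would give the lower groups less. The second group exceeded the top one in each pair of libraries, but its median differed as much between the WT libraries used (0.33 and 0.64 for nrpd1a replicate 1). The loss of Pol IV and a difference in the cells collected stay open as untested.

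At a coverage of 10 the CHH level was higher by 0.443 percentage points and the CHG level by 1.32 in nrpd1a leaves. Over the cytosines covered 10 times in every library the differences were -0.00271 points for CHH (WT SD 0.303) and 0.152 points for CHG (WT SD 0.519). Both lie within their spread, so different cytosines passing the minimum in each library cannot be told apart from a difference between the genotypes there. No biological explanation was tested for this turn.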
